A study of Drosophila melanogaster with 29 samples.

How the data were processed

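RNA was extracted from whole flies with Trizol and a silica column with DNase treatment, per the labels' protocols, and polyadenylated RNA was sequenced as paired-end reads of 150 bp. Reads were mapped with STAR 2.5.2b to build BDGP6 and counted with featureCounts of Subread 1.5.2, per the submitters' processing notes. The annotation release, the strand setting and the treatment of reads with several matches are not given in the sources used here. Read counts per gene were deposited by the authors as one table of raw whole-number counts, with 17411 genes and 29 libraries, and no normalisation. Every column was matched to a library by its title, and the groups were taken from the titles.

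Gene identifiers in the table were matched to an Ensembl annotation of BDGP6 for positions and current symbols. Of the identifiers, 17137 matched and 274 did not, and 139 entries have no gene name in the table. Coordinates are those of that annotation, which may be a later release than the one used for counting. Genes with overlapping exons or near-identical copies are reported as uncertain, because reads could be split between them and the use of strand is not known.

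Total counts per library ranged from 12260798 to 17438360. Counts were analysed with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 in R 4.3.3. F and M libraries were fitted separately, each with its 3 arms sharing one dispersion estimate, because whole female and male flies differ in germline tissue. Libraries were scaled by TMM, genes of low count were removed with filterByExpr at its default settings, and differences were tested with edgeR's quasi-likelihood F test, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. This left 10503 genes in F and 13072 in M. The biological coefficient of variation was 0.246 in F and 0.141 in M, and the first principal component held 58.2% of the variance in F and 37.9% in M. The SE of a log2 fold change was computed as its size divided by the square root of the F statistic. Whether an arm difference itself differed between the sexes was tested as an interaction in one fit of the 6 groups.

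Gene lists, 43 in number, were tested with limma camera at a preset inter-gene correlation of 0.01, with adjustment over the lists of at least 3 measured members. The same test with a correlation estimated for each list, and limma's fry, stand beside it. Members counted as rose or fell passed the edgeR test of the same comparison, and a second count adjusts over the list alone. The comparisons, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. Another list, for the maturation of the adult cuticle, was added after the data had been seen.

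Named genes passed the test, had a mean log2 CPM of at least 1 and a symbol other than a computed or non-coding gene number, and had all libraries of one arm above all of the other. For Q88 against WT these were the 10 that rose most and the 10 that fell most, and for each comparison with CTRL the 5 and 5. For each interaction the 3 and 3 with the largest differences were taken without the condition on separation. To these were added up to 4 members of each described list, those with the smallest adjusted p, and the fixed genes Gug, Yp1, Yp2, Yp3, roX1, roX2, Acp26Aa and Mst98Ca. Genes outside this rule are marked as chosen after their values were seen.

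The test was checked on simulated counts drawn from the means and library sizes of these libraries, with 200 changed genes in each comparison. For Q88 against WT it recovered 29.9%, 58.2% and 93.9% of the genes changed 1.5-fold, 2-fold and 4-fold among 10503 genes in F, and 64.2%, 86.6% and 98.5% among 13072 genes in M. For Q88 against CTRL the shares were 29.9%, 62.7% and 97.0% of 10503 genes in F and 65.7%, 97.0% and 100% of 13072 genes in M. For WT against CTRL they were 17.9%, 53.7% and 92.4% of 10503 genes in F and 55.2%, 82.1% and 97.0% of 13072 genes in M. False calls numbered 2 of 123, 6 of 132 and 3 of 112 in F and 8 of 174, 8 of 183 and 6 of 162 in M, in the same order. The simulated genes were drawn independently of each other. These shares therefore do not cover variation between libraries that many genes have in common.

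Libraries of one group were compared for duplicates by a chi-square per gene, which lay between 3.85 and 291.15 over all pairs, so no pair came within sampling noise. The alternatives were DESeq2, RLE size factors, no filter on low counts, each library left out in turn, a replicate block, only the 2 compared arms, all 6 groups in one fit, and, chosen after the data had been seen, the cuticle maturation score as a covariate and the removal of both F libraries at the ends of the first component. Other splits of the samples were drawn 100 times for each comparison of arms and 40 times for each interaction. Shared controls were examined with 20 simulations without effect and 10 splits of the CTRL libraries. Counting intervals cover counting error only.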

Results

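Polyadenylated RNA of whole Drosophila melanogaster was sequenced as paired-end reads of 150 bp in 29 libraries. The flies belong to a model of dentatorubral-pallidoluysian atrophy, an inherited neurodegenerative disease in which the polyglutamine repeat of the ATN1 protein is expanded. The libraries fell into 3 arms, labelled CTRL, WT and Q88, each with an F and an M group. There were 5 libraries in every group except WT F, which had 4. Q88 names the pathogenic repeat of human ATN1. The labels do not spell out that WT is the normal-repeat transgene, nor what the CTRL flies carry, so the arms are named by their labels throughout. Total counts ranged from 12260798 to 17438360 per library. Nothing in the labels says that libraries of one group came from separate pools of flies, so the p-values measure only the spread between these samples, which may be technical. Values per gene are CPM after TMM scaling. Fold changes are log2 values with their standard error (SE).

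The F and M marks were checked with sex-specific transcripts. Yp1 (FBgn0004045, chromosome X, 10053811 to 10055498, build BDGP6), a yolk protein gene, lay between 3210 and 6440 CPM in the F libraries and at or below 0.339 CPM in the M libraries. The male-specific dosage-compensation RNA roX1 lay between 462 and 735 CPM in M and at or below 9.62 CPM in F. Acp26Aa (FBgn0002855, chromosome 2L, 5892883 to 5893896), a seminal fluid protein gene of the male accessory gland, ranged from 219 to 513 CPM in M and reached at most 0.139 CPM in F. The testis transcript Mst98Ca ranged from 330 to 635 CPM in M and reached at most 0.0671 CPM in F. Every library matched its mark. Yp1 shares exon sequence with an antisense gene and roX1 with ec, and strand use in the counting is not given in the sources used here.

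Gug (FBgn0010825, chromosome 3L, 8449922 to 8472669), the fly Atrophin and homologue of human ATN1, did not pass the edgeR test in any comparison of arms. In F it averaged 261 ± 50.5 CPM (SD, n = 5) in Q88, 210 ± 21.2 CPM (SD, n = 4) in WT and 241 ± 46.8 CPM (SD, n = 5) in CTRL. In M the means were 111 ± 14.8 CPM in Q88, 127 ± 6.76 CPM in WT and 104 ± 18.3 CPM in CTRL (SD, n = 5 each). The log2 difference between Q88 and WT was 0.31 ± 0.16 in F (SE, edgeR adjusted p = 0.482) and -0.19 ± 0.12 in M (SE, edgeR adjusted p = 0.236). The human transgene itself was not analysed here.

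**Figure D1:**
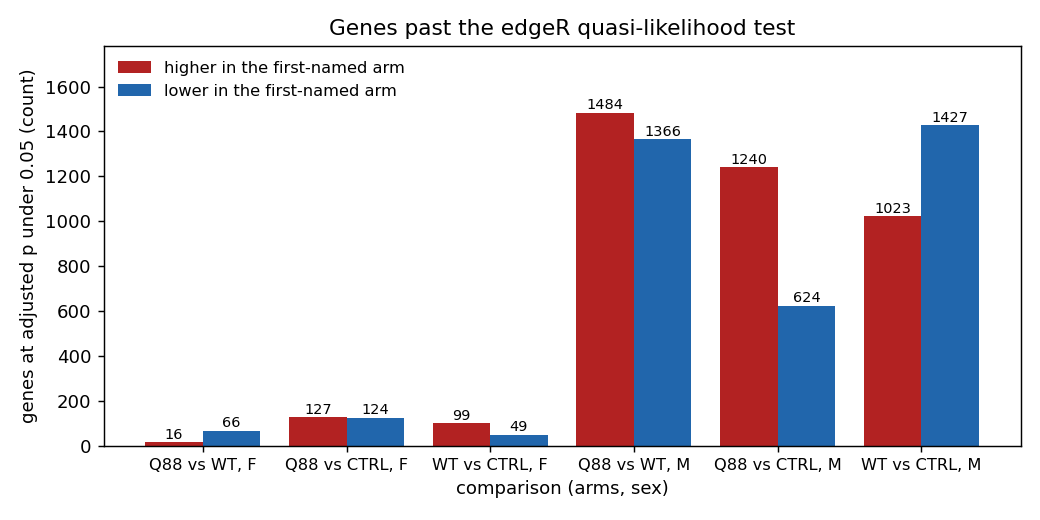
Number of genes past the edgeR quasi-likelihood test in each comparison of arms, with bars for genes higher and genes lower in the first-named arm. Counts were 16 and 66 for Q88 against WT in F and 1484 and 1366 for the same comparison in M.

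Q88 was compared with WT to ask which transcripts differed between the pathogenic repeat and the WT arm. In F flies, a set of heat-shock genes was lower in Q88 than in WT, while a serine protease gene and the glutathione S-transferase genes GstD2 and GstD9 were higher. Hsp67Bc (FBgn0001229, chromosome 3L, 9371511 to 9372497), which encodes a small heat-shock protein, averaged 12.8 ± 3.39 CPM (SD, n = 5) in Q88 and 69.4 ± 7.72 CPM (SD, n = 4) in WT, a log2 change of -2.44 ± 0.20 (SE, edgeR adjusted p = 7.12e-05). The trypsin-like serine protease gene Ser12 (FBgn0011832, chromosome 2L, 2250431 to 2251275) averaged 16.0 ± 5.84 CPM (SD, n = 5) in Q88 and 0.266 ± 0.201 CPM (SD, n = 4) in WT, where it had 15 reads in all, a log2 change of 5.89 ± 0.51 (SE, edgeR adjusted p = 8.18e-05). GstD2 (FBgn0010038, chromosome 3R, 12371971 to 12372704), a detoxifying glutathione S-transferase gene, rose from 5.48 ± 1.72 CPM (SD, n = 4) to 19.1 ± 3.14 CPM (SD, n = 5). For GstD2 the log2 change was 1.80 ± 0.27 (SE, edgeR adjusted p = 0.00641). CTRL F averaged 16.55 CPM of Hsp67Bc, close to Q88. It averaged 0.0270 CPM of Ser12 and 8.33 CPM of GstD2, closer to WT.

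Further genes that were lower in Q88 F included Hsp68 (FBgn0001230, chromosome 3R, 24055080 to 24057310), an Hsp70-family chaperone gene, at 299 ± 77.7 CPM (SD, n = 5) against 714 ± 247 CPM (SD, n = 4). For Hsp68 the log2 change was -1.26 ± 0.24 (SE). Cyp6a23, a cytochrome P450 gene, fell by 1.59 ± 0.17 on the log2 scale (SE, edgeR adjusted p = 7.09e-04). Pepck2 (FBgn0034356, chromosome 2R, 18527430 to 18535749), which encodes a gluconeogenic enzyme, fell by 1.26 ± 0.21 (SE, edgeR adjusted p = 0.0133), and hll fell by 1.44 ± 0.30 (SE, edgeR adjusted p = 0.0416). CTRL F averaged 136 CPM of Hsp68, below Q88. For Cyp6a23 and Pepck2 the CTRL F means of 16.2 and 13.8 CPM lay near those of Q88, 15.8 and 14.7 CPM. For hll the CTRL F mean of 20.4 CPM lay nearer WT, at 22.5 CPM, than Q88, at 8.25 CPM. Of the genes that rose, fit (FBgn0038914, chromosome 3R, 21883924 to 21884454), a fat-body gene with female-enriched expression, averaged 57.4 ± 12.8 CPM (SD, n = 5) in Q88 and 17.1 ± 4.69 CPM (SD, n = 4) in WT, a log2 change of 1.75 ± 0.34 (SE, edgeR adjusted p = 0.0303). GstD9 rose by 0.73 ± 0.15 and Gnpat, an enzyme gene of ether-lipid synthesis, by 0.55 ± 0.11 on the log2 scale (SE). chrb, a homologue of the TOR inhibitor REDD1, rose by 0.29 ± 0.06 on the log2 scale (SE, edgeR adjusted p = 0.0424). For each of the genes named so far in this comparison, all libraries of one arm lay above all libraries of the other. The exons of fit, Gnpat and Hsp68 overlap those of other genes, so their counts are uncertain by that share.

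By list, 8 of the 27 measured heat-shock and chaperone genes fell in Q88 F and the other 19 did not pass the test over all genes; 10 fell and 1 rose when adjusted over the list alone (limma camera adjusted p = 2.37e-08; adjusted p = 0.65 with an estimated correlation). The members that fell included 5 copies of Hsp70, between -1.91 ± 0.26 for Hsp70Ba and -1.26 ± 0.17 for Hsp70Bb on the log2 scale (SE), whose near-identical sequences leave the split of reads between copies uncertain. Of 44 odorant-binding and olfactory genes, 5 fell, and 6 fell adjusted over the list alone (limma camera adjusted p = 4.36e-04; adjusted p = 0.706 with an estimated correlation). WT F was itself above CTRL F for Obp56d and the receptor gene Ir51a, by 0.52 ± 0.09 and 2.95 ± 0.42 (log2, SE). Obp56a was lower in Q88 F than in CTRL F, at -1.444 ± 0.205 (log2, SE). In Q88 against WT, Obp56d fell by 0.62 ± 0.09, Obp56a by 1.18 ± 0.21 and Ir51a by 2.15 ± 0.38 on the log2 scale (SE). Of 58 digestive enzyme genes, 3 fell and 1 rose, and 16 fell and 1 rose adjusted over the list alone (limma camera adjusted p = 9.76e-06; adjusted p = 0.65 with an estimated correlation). The gut serine protease genes Jon99Fi and lambdaTry fell by 1.01 ± 0.17 and 1.08 ± 0.18, and the lysozyme gene LysD by 0.92 ± 0.17 on the log2 scale (SE). Of 79 cytochrome P450 genes, 3 fell, and 10 fell and 2 rose adjusted over the list alone (limma camera adjusted p = 1.71e-04; adjusted p = 0.706 with an estimated correlation). Beside Cyp6a23, the genes that fell were Cyp6a2 and Cyp6a9, at -0.95 and -0.75 on the log2 scale. Of 28 lipid metabolism genes, 2 fell, the acyl-CoA dehydrogenase gene Mcad by 0.38 ± 0.07 and the intestinal lipase gene mag by 0.45 ± 0.09 on the log2 scale (SE); 4 fell adjusted over the list alone (limma camera adjusted p = 0.0020; adjusted p = 0.660 with an estimated correlation). Mcad and mag were higher in WT F than in CTRL F, by 0.35 ± 0.07 and 0.62 ± 0.09 (log2, SE). In Q88 against WT, the 35 glutathione S-transferase genes moved both ways, with 2 that rose and 2 that fell, or 5 and 3 adjusted over the list alone. The list was not called, and its median of -0.01 differed in sign from its mean of 0.09 and from the test (limma camera adjusted p = 0.469; adjusted p = 0.725 with an estimated correlation). GstT4 and GstZ2 fell by 0.69 ± 0.10 and 0.68 ± 0.14 on the log2 scale (SE).

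In all, 82 of 10503 tested genes passed the edgeR test in F, 16 higher and 66 lower in Q88, of which 7 and 25 changed at least 2-fold. In 6.1% of the tested genes all libraries of one arm lay above all of the other, against 1.59% expected by chance. The count was 46 with the replicate block, 330 with DESeq2, 227 with all 6 groups in one fit, 163 without both libraries at the ends of the first principal component (CTRL F 3 and Q88 F 2) and 2871 with the cuticle maturation score described for M as a covariate. Leaving out 1 library gave 44, 45 and 43 genes without Q88 F 2, 3 and 5, and 46 and 35 genes without WT F 4 and 5. In the same runs chrb lost its call without any 1 of the 9 libraries, GstD9 without any except Q88 F 1, Gnpat without any except Q88 F 4 and WT F 1, fit without any except Q88 F 1 and 4, hll without any except Q88 F 1 and WT F 3, and Hsp68 without Q88 F 2, 3 or 5 or WT F 1 or 5, with edgeR adjusted p of at most 0.145, 0.139, 0.103, 0.103, 0.133 and 0.0962. Hsp70Aa lost its call without Q88 F 3 or 5 or WT F 1 or 5, at an adjusted p of at most 0.0911.

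In M flies, most genes of the accessory gland list and part of the digestive enzyme and glutathione S-transferase genes were higher in Q88 than in WT, and part of the heat-shock, antimicrobial peptide, neuron and phototransduction genes were lower. Acp26Aa averaged 482 ± 38.8 CPM in Q88 and 251 ± 34.7 CPM in WT (SD, n = 5 each). For Acp26Aa the log2 change was 0.95 ± 0.13 (SE, edgeR adjusted p = 1.98e-04). GstD2 averaged 22.6 ± 1.74 CPM against 4.43 ± 0.754 CPM (SD, n = 5 each). For GstD2 the log2 change was 2.35 ± 0.20 (SE, edgeR adjusted p = 6.83e-06). Npc1b (FBgn0261675, chromosome X, 20934869 to 20939503), which acts in sterol uptake by the midgut, averaged 96.8 ± 17.5 CPM against 20.5 ± 3.64 CPM (SD, n = 5 each). For Npc1b the log2 change was 2.24 ± 0.25 (SE, edgeR adjusted p = 3.94e-05). HSPBAP1 (FBgn0263025, chromosome 3R, 27695235 to 27696531) averaged 2.47 ± 0.580 CPM in Q88 and 37.7 ± 8.81 CPM in WT (SD, n = 5 each). For HSPBAP1 the log2 change was -3.93 ± 0.19 (SE, edgeR adjusted p = 8.42e-09). CTRL M averaged 2.70 CPM of HSPBAP1, near Q88. It averaged 279 CPM of Acp26Aa, 5.38 CPM of GstD2 and 19.8 CPM of Npc1b, near WT.

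Among the other genes that rose most in Q88 M, fit went from 0.444 ± 0.165 to 7.11 ± 4.88 CPM (SD, n = 5 each). For fit the log2 change was 3.99 ± 0.46 (SE, edgeR adjusted p = 4.93e-05). Jon25Biii (FBgn0031653, chromosome 2L, 4949941 to 4950767), a gut serine protease gene, averaged 653 ± 119 CPM against 182 ± 108 CPM (SD, n = 5 each). For Jon25Biii the log2 change was 1.85 ± 0.34 (SE, edgeR adjusted p = 0.00173). PpD6 (FBgn0005779, chromosome 2L, 3109672 to 3110998) averaged 9.34 ± 0.905 CPM against 2.82 ± 0.509 CPM (SD, n = 5 each). For PpD6 the log2 change was 1.72 ± 0.12 (SE, edgeR adjusted p = 5.11e-07). The CTRL M mean of PpD6, 9.07 CPM, lay near Q88, while those of fit and Jon25Biii, 0.665 and 218 CPM, lay near WT. IntS12 rose by 1.67 ± 0.14, Acsx1L by 1.73 ± 0.24 and the odorant-binding protein gene Obp56h by 1.77 ± 0.23 on the log2 scale (SE). PGRP-SC1a, which encodes a peptidoglycan-cleaving amidase, rose by 1.77 ± 0.49 on the log2 scale (SE, edgeR adjusted p = 0.0202), a call that was lost without WT M 1 or WT M 2, at an adjusted p of at most 0.0514. Of the genes that fell, the maltase gene Mal-B1 (FBgn0032381, chromosome 2L, 11847226 to 11849169) averaged 35.8 ± 16.2 CPM in Q88 and 105 ± 30.7 CPM in WT (SD, n = 5 each). For Mal-B1 the log2 change was -1.56 ± 0.29 (SE, edgeR adjusted p = 0.00181). Acp98AB (FBgn0263597, chromosome 3R, 27694883 to 27695057), which lies next to HSPBAP1, fell by 2.01 ± 0.22 on the log2 scale (SE, edgeR adjusted p = 3.53e-05). The genes cysu and Lime fell by 2.41 ± 0.50 and 2.22 ± 0.46, and Cyp4e3 by 1.90 ± 0.36 on the log2 scale (SE). In all of the genes named by rank in this comparison, every library of one arm lay above every library of the other, and the exons of HSPBAP1 overlap those of ALiX.

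In the accessory gland and ejaculatory bulb list, 54 of 66 genes rose and 1 fell, or 57 and 2 adjusted over the list alone, with a median log2 change of 0.81 (limma camera adjusted p = 2.02e-38; adjusted p = 0.342 with an estimated correlation). Acp24A4 rose by 1.21 ± 0.12, Spn77Bb by 1.63 ± 0.16 and Sfp93F by 1.40 ± 0.15 on the log2 scale (SE), and the member that fell was Acp98AB. The accessory gland score, the mean over members of z-scaled log2 CPM, was 0.963 ± 0.196 in Q88, -0.671 ± 0.445 in WT and -0.292 ± 0.602 in CTRL (SD, n = 5 each). Of 56 testis and sperm genes, 20 rose, and 28 rose and 1 fell adjusted over the list alone (limma camera adjusted p = 1.85e-06; adjusted p = 0.589 with an estimated correlation). They included the sperm protein gene dj, at 0.43 ± 0.09 on the log2 scale (SE), and Mst57Da, Mst57Db and Mst57Dc, which are transcripts of the accessory gland. Of 56 digestive enzyme genes, 22 rose and 1 fell, or 26 and 1 adjusted over the list alone (limma camera adjusted p = 2.95e-09; adjusted p = 0.5003 with an estimated correlation). The WT libraries differed among themselves, with a digestive enzyme score of 0.449 in WT M 3, inside the Q88 range of 0.402 to 0.722, 0.167 in WT M 4, and -0.9035, -1.15 and -1.03 in WT M 1, 2 and 5. The trypsin genes thetaTry and etaTry rose by 1.33 ± 0.20 and 0.71 ± 0.11 and Npc2e by 3.22 ± 0.54 on the log2 scale (SE). Jon66Ci rose by 2.61 ± 0.42 on the log2 scale (SE), with Jon66Cii as a close paralogue that shares sequence.

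Of 35 glutathione S-transferase genes, 15 rose and 3 fell, or 16 and 3 adjusted over the list alone (limma camera adjusted p = 1.85e-06; adjusted p = 0.412 with an estimated correlation). GstD1 rose by 0.74 ± 0.11, GstD5 by 1.30 ± 0.18 and GstD10 by 1.49 ± 0.23 on the log2 scale (SE). Of 20 antioxidant genes, 7 rose and 2 fell, or 8 and 2 adjusted over the list alone (limma camera adjusted p = 0.0199; adjusted p = 0.412 with an estimated correlation). Among them were Gclm and Gclc, which encode the subunits of the enzyme that starts glutathione synthesis, at 0.66 ± 0.07 and 0.48 ± 0.09 on the log2 scale (SE). Of 82 cytochrome P450 genes, 27 rose and 8 fell, or 29 and 10 adjusted over the list alone (limma camera adjusted p = 0.0046; adjusted p = 0.641 with an estimated correlation), with Cyp9b2 at 0.94 ± 0.15 and Cyp4ac3 at -1.40 ± 0.17 (log2, SE). Of 18 genes of the unfolded protein response of the endoplasmic reticulum, 7 rose, and 7 rose and 1 fell adjusted over the list alone (limma camera adjusted p = 0.0175; adjusted p = 0.412 with an estimated correlation). The disulphide isomerase genes Pdi and CaBP1 rose by 0.37 and 0.46 on the log2 scale.

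Of 29 heat-shock genes, 13 fell and 2 rose in Q88 against WT in M, or 14 and 4 adjusted over the list alone (limma camera adjusted p = 2.53e-05; adjusted p = 0.412 with an estimated correlation). Hsp67Bc averaged 18.2 ± 2.11 CPM in Q88 and 107 ± 42.4 CPM in WT (SD, n = 5 each). For Hsp67Bc the log2 change was -2.55 ± 0.25 (SE, edgeR adjusted p = 1.47e-05), and Hsp70Ba fell by 2.19 ± 0.23 on the log2 scale (SE). The CTRL M mean of Hsp67Bc, 18.3 CPM, lay near that of Q88. The heat-shock score was 1.09 and 0.736 in WT M 3 and 4 and 0.381 in WT M 5, but 0.0179 and -0.0086 in WT M 1 and 2, inside the Q88 range of -0.0336 to 0.292, so the difference of this score lay mainly in WT M 3 and 4. Hsp67Bc itself had 72.4 and 56.2 CPM in WT M 1 and 2, against at most 20.3 CPM in Q88 M. Of 34 antimicrobial peptide and Bomanin genes, 10 fell and 1 rose, or 11 and 2 adjusted over the list alone (limma camera adjusted p = 0.0030; adjusted p = 0.541 with an estimated correlation), with BomS3 at -1.27 and BomBc2 at -1.03 on the log2 scale. Of 34 phototransduction genes, 11 fell both over all genes and adjusted over the list alone (limma camera adjusted p = 0.0037; adjusted p = 0.412 with an estimated correlation), among them ninaC by 0.65 ± 0.08 and norpA, the phospholipase C of photoreceptors, by 0.39 ± 0.09 on the log2 scale (SE). Of 26 neuron and synapse genes, 8 fell and 1 rose, or 12 and 1 adjusted over the list alone (limma camera adjusted p = 2.73e-04; adjusted p = 0.5003 with an estimated correlation). In F no gene of this list passed between Q88 and WT (lowest edgeR adjusted p = 0.505, for onecut). The RNA came from whole flies, and the share of each tissue in it was not measured, for this or any other list. In M the transmitter-system genes VGlut, ChAT and Gad1 fell by 0.39, 0.36 and 0.40 on the log2 scale. Of 17 glial genes, 5 fell, and 6 fell adjusted over the list alone (limma camera adjusted p = 0.0199; adjusted p = 0.5003 with an estimated correlation), including the glial transcription factor gene repo by 0.45 on the log2 scale.

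A total of 2850 of 13072 tested genes passed the edgeR test in M, 1484 higher and 1366 lower in Q88, of which 212 and 183 changed at least 2-fold. In 15.7% of the tested genes all libraries of one arm lay above all of the other, against 0.79% expected by chance. A score for the maturation of the adult cuticle, from a list added after the data had been seen, was -0.660 ± 0.185 in Q88, 0.356 ± 0.848 in WT and 0.304 ± 0.593 in CTRL (SD, n = 5 each). It was -0.836 and -0.167 in WT M 3 and 4 and between 0.678 and 1.28 in the other WT M libraries, from which WT M 3 and 4 also stood apart on the first principal component, at 11.07 and 1.60 against -44.3 to -28.08. With this score as a covariate 1167 genes passed, 838 of them among the 2850 in the same direction, and the limma camera calls of the antimicrobial peptide, cytochrome P450 and glial lists were lost (adjusted p = 0.626, 0.669 and 0.274). With all 6 groups in one fit 1410 genes passed. Leaving out 1 library gave 1791, 1675 and 1800 genes without Q88 M 1, 3 and 5 and 1802 without WT M 1.

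**Figure D2:**
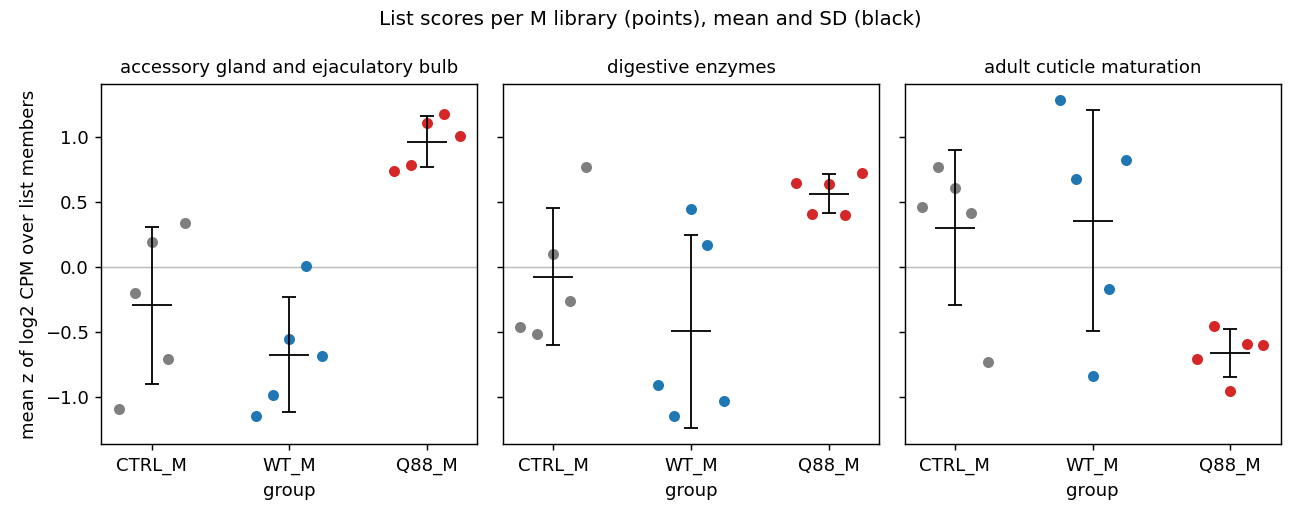
Scores of 3 gene lists in each M library, on an axis of mean z-scaled log2 CPM over the list's members, for the accessory gland, digestive enzyme and adult cuticle maturation lists. Points are libraries, with black marks for the mean ± SD of each arm (n = 5), and the accessory gland score averaged 0.963 in Q88 and -0.671 in WT.

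WT was compared with CTRL to show how the WT arm, on its own, differed from the flies labelled control. In F, part of the heat-shock genes and an ABC transporter gene were higher in WT, and the cytochrome P450 genes Cyp6a2, Cyp4p2 and Cyp4d21 and the lysozyme gene LysD were lower. Hsp68 averaged 714 ± 247 CPM (SD, n = 4) in WT and 136 ± 24.0 CPM (SD, n = 5) in CTRL, a log2 change of 2.39 ± 0.25 (SE, edgeR adjusted p = 1.21e-04). The ABC transporter gene FBgn0010549 (chromosome 2R, 9390165 to 9395281) averaged 15.8 ± 0.840 CPM (SD, n = 4) against 1.40 ± 0.362 CPM (SD, n = 5). For FBgn0010549 the log2 change was 3.49 ± 0.16 (SE, edgeR adjusted p = 5.94e-08). Cyp6a2 (FBgn0000473, chromosome 2R, 6779749 to 6781491) averaged 12.0 ± 0.789 CPM (SD, n = 4) in WT and 112 ± 22.0 CPM (SD, n = 5) in CTRL, a log2 change of -3.22 ± 0.17 (SE, edgeR adjusted p = 2.40e-07).

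The heat-shock list had 10 of 27 members that rose in WT F, or 15 adjusted over the list alone, with a median log2 change of 0.64 (limma camera adjusted p = 2.99e-29; adjusted p = 0.0332 with an estimated correlation). Hsp70Bb (FBgn0013278, chromosome 3R, 12505793 to 12508139) averaged 111 ± 18.9 CPM (SD, n = 4) against 20.4 ± 4.48 CPM (SD, n = 5). For Hsp70Bb the log2 change was 2.45 ± 0.18 (SE, edgeR adjusted p = 3.54e-06), and Hsp67Bc rose by 2.07 ± 0.20 on the log2 scale (SE). Of 79 cytochrome P450 genes, 3 rose and 4 fell, or 8 and 9 adjusted over the list alone. There was no call, and the median of 0.07 differed in sign from the mean of -0.04 and from the test (limma camera adjusted p = 0.765; adjusted p = 0.988 with an estimated correlation). Cyp4p2 (FBgn0033395, chromosome 2R, 9237512 to 9239831) and Cyp4d21 fell by 4.14 ± 0.24 and 2.31 ± 0.30 on the log2 scale (SE). Cyp6a23 rose by 1.56 ± 0.17 on the log2 scale (SE). Of 58 digestive enzyme genes, 5 rose and 5 fell, or 15 and 6 adjusted over the list alone, with no call (limma camera adjusted p = 0.258; adjusted p = 0.988 with an estimated correlation). Jon66Ci rose by 2.49 ± 0.39, while LysD (FBgn0004427, chromosome 3L, 1210717 to 1211196) fell by 3.10 ± 0.19 on the log2 scale (SE). LysD overlaps the pseudogene LysC, which fell by 3.03 ± 0.21 (SE), so their reads cannot be assigned with certainty.

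Of 10503 genes, 148 passed the edgeR test in this F comparison, 99 higher and 49 lower in WT, of which 54 and 29 changed at least 2-fold. Complete separation of the arms was seen in 4.3% of tested genes, against 1.59% expected by chance, and held for each gene named by rank. DESeq2 called 305 genes, a fit of all 6 groups 258, the fit without CTRL F 3 and Q88 F 2 399, and the cuticle maturation score as a covariate 477. Leaving out 1 library gave 95, 97 and 97 genes without CTRL F 1, 2 and 4 and 95 and 92 without WT F 1 and 5.

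**Figure D3:**
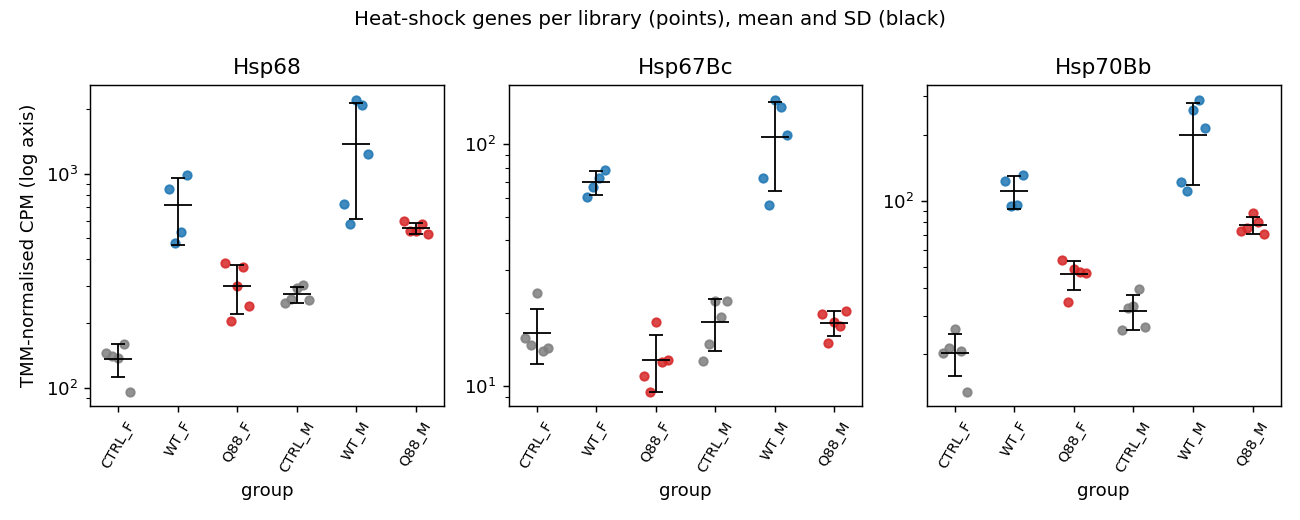
Expression of Hsp68, Hsp67Bc and Hsp70Bb in each library of the 6 groups, in TMM-scaled CPM on a log axis. Points are libraries and black marks the mean ± SD (n = 5, n = 4 for WT F), with Hsp68 at 714 CPM in WT F, 299 in Q88 F and 136 in CTRL F.

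In M, most genes of the heat-shock list and part of the haemocyte and antimicrobial peptide genes were higher in WT than in CTRL, and most genes of the testis list and a few of the digestive enzyme genes were lower. Hsp70Bb averaged 200 ± 80.7 CPM in WT and 31.6 ± 5.70 CPM in CTRL (SD, n = 5 each). For Hsp70Bb the log2 change was 2.66 ± 0.23 (SE, edgeR adjusted p = 2.88e-06). HSPBAP1 averaged 37.7 ± 8.81 CPM against 2.70 ± 0.643 CPM (SD, n = 5 each). For HSPBAP1 the log2 change was 3.81 ± 0.19 (SE, edgeR adjusted p = 1.08e-08), and its neighbour Acp98AB rose by 3.05 ± 0.25 on the log2 scale (SE). The antimicrobial peptide gene DptB averaged 24.5 ± 23.0 CPM in WT and 1.08 ± 0.363 CPM in CTRL (SD, n = 5 each). For DptB the log2 change was 4.50 ± 0.83 (SE, edgeR adjusted p = 0.00256), and DptA rose by 3.88 ± 0.93 on the log2 scale (SE, edgeR adjusted p = 0.0118), or by 3.18 without WT M 5. DptB overlaps the exons of CG43109. Another antimicrobial peptide gene, Drsl3 (FBgn0052283, chromosome 3L, 3314996 to 3315355), averaged 0.0515 ± 0.0292 CPM in WT, with 4 reads in all, and 5.23 ± 4.07 CPM in CTRL (SD, n = 5 each). For Drsl3 the log2 change was -6.39 ± 1.09 (SE, edgeR adjusted p = 0.00155).

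The heat-shock list had 16 of 29 members that rose and 2 that fell in WT M, or 17 and 3 adjusted over the list alone (limma camera adjusted p = 9.02e-15; adjusted p = 0.178 with an estimated correlation). Of 22 haemocyte genes, 9 rose and 1 fell, or 11 and 1 adjusted over the list alone (limma camera adjusted p = 1.73e-05; adjusted p = 0.178 with an estimated correlation). Pxn rose by 0.56 ± 0.07, and the phagocytic receptor genes crq and NimC1 by 0.52 and 0.64 on the log2 scale. Of 34 antimicrobial peptide and Bomanin genes, 10 rose and 2 fell, or 11 and 3 adjusted over the list alone (limma camera adjusted p = 0.0156; adjusted p = 0.780 with an estimated correlation), with AttB at 2.59 ± 0.27 (log2, SE). Of 56 testis and sperm genes, 33 fell, or 37 adjusted over the list alone, with a median log2 change of -0.30 (limma camera adjusted p = 5.30e-13; adjusted p = 0.702 with an estimated correlation). The sperm protein genes dj and Mst84Dd fell by 0.50 ± 0.09 and 0.54 ± 0.10 and Mst98Ca by 0.29 ± 0.09 on the log2 scale (SE). Of 82 cytochrome P450 genes, 9 rose and 19 fell, with the same counts adjusted over the list alone (limma camera adjusted p = 0.0048; adjusted p = 0.780 with an estimated correlation). Cyp6a2 fell by 3.41 ± 0.21 and Cyp4p2 by 3.68 ± 0.20 on the log2 scale (SE). Of 56 digestive enzyme genes, 9 fell and 1 rose, or 9 and 2 adjusted over the list alone (limma camera adjusted p = 0.0142; adjusted p = 0.860 with an estimated correlation), with Jon44E at -2.34 ± 0.21 (log2, SE) and LysD at -2.71 ± 0.32. The digestive enzyme score of WT M 3 and 4 lay inside the CTRL range of -0.5165 to 0.766, and that of WT M 1, 2 and 5 below it. The upper end of this range was CTRL M 5 alone. The other CTRL M libraries reached at most 0.104, below WT M 3 and 4. Of 28 lipid metabolism genes, 9 rose and 1 fell, or 11 and 2 adjusted over the list alone (limma camera adjusted p = 0.0142; adjusted p = 0.780 with an estimated correlation), among them the beta-oxidation genes Mcad, by 0.97, and Mtpalpha, by 0.67 on the log2 scale.

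A total of 2450 of 13072 genes passed the edgeR test between WT and CTRL in M, 1023 higher and 1427 lower in WT, of which 126 and 138 changed at least 2-fold. Complete separation was seen in 11.6% of tested genes, against 0.79% expected by chance, and held for each gene named by rank. The count was 1034 with only these 2 arms in the fit, 719 with all 6 groups in one fit and 3942 with the cuticle maturation score as a covariate, where the antimicrobial peptide list lost its call (limma camera adjusted p = 0.1195). It was 1503 without CTRL M 5 and 1600 without WT M 1.

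Q88 was compared with CTRL to show how the pathogenic repeat differed from the flies labelled control. In F, Ser12, the ABC transporter gene FBgn0010549 and the stress-linked transcription factor gene Ets21C were higher in Q88, and the cytochrome P450 genes Cyp4p2, Cyp6a2 and Cyp4d21 and the lysozyme genes LysD and LysE were lower. Ser12 averaged 16.0 ± 5.84 CPM in Q88 and 0.0270 ± 0.0603 CPM in CTRL (SD, n = 5 each), where it had 2 reads in all, a ratio with a counting interval from 165 to 4930 at the 95% level. FBgn0010549 averaged 18.1 ± 1.41 CPM against 1.40 ± 0.362 CPM (SD, n = 5 each). For FBgn0010549 the log2 change was 3.68 ± 0.16 (SE, edgeR adjusted p = 1.11e-08). Cyp6a2 averaged 6.23 ± 1.12 CPM against 112 ± 22.0 CPM (SD, n = 5 each). For Cyp6a2 the log2 change was -4.17 ± 0.17 (SE, edgeR adjusted p = 9.66e-09). LysD averaged 22.2 ± 3.55 CPM against 360 ± 68.4 CPM (SD, n = 5 each). For LysD the log2 change was -4.02 ± 0.18 (SE, edgeR adjusted p = 1.90e-08).

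Cyp4p2 fell by 4.88 ± 0.23 on the log2 scale in Q88 F (SE, edgeR adjusted p = 2.44e-08), and Jon66Ci and the acyl-CoA-binding protein gene Acbp6 rose by 2.68 ± 0.38 and 2.17 ± 0.35 (SE). Ets21C (FBgn0005660, chromosome 2L, 544925 to 552923) averaged 8.44 ± 4.07 CPM against 1.64 ± 1.00 CPM (SD, n = 5 each). For Ets21C the log2 change was 2.36 ± 0.45 (SE, edgeR adjusted p = 0.0115), and its exons overlap those of nAChRbeta3. It belongs to a list of 20 genes of JNK signalling, apoptosis and DNA damage, of which 3 rose, with the same count adjusted over the list alone. The list was not called, and its median of -0.004 differed in sign from its mean of 0.11 and from the test (limma camera adjusted p = 0.170; adjusted p = 0.815 with an estimated correlation). The other members that rose were puc, the JNK phosphatase gene, by 0.56 ± 0.12 and Jra, the fly Jun, by 0.40 ± 0.10 on the log2 scale (SE). Of 27 heat-shock genes, 3 rose, with the same count adjusted over the list alone (limma camera adjusted p = 4.76e-06; adjusted p = 0.815 with an estimated correlation). They were Hsp70Bb at 1.19 ± 0.17, Hsp68 at 1.14 ± 0.23 and Hsp83 at 0.48 ± 0.08 (log2, SE). Of 79 cytochrome P450 genes, 3 rose and 7 fell, or 5 and 11 adjusted over the list alone (limma camera adjusted p = 4.47e-05; adjusted p = 0.815 with an estimated correlation), with Cyp4p1 at 1.30 ± 0.14 (log2, SE) and Cyp4d21 at -2.60. Of 58 digestive enzyme genes, 6 rose and 9 fell, or 8 and 11 adjusted over the list alone (limma camera adjusted p = 0.0084; adjusted p = 0.815 with an estimated correlation), with LysE at -2.67 ± 0.21 (log2, SE) and Jon44E at -1.59. Of 35 glutathione S-transferase genes, 1 rose and 4 fell, or 3 and 5 adjusted over the list alone, with no call (limma camera adjusted p = 0.791; adjusted p = 0.955 with an estimated correlation), and the member that rose was GstD2 at 1.19 ± 0.24 (log2, SE). ImpL2, which encodes a secreted insulin antagonist and was chosen after its values were seen, rose by 1.22 ± 0.20 on the log2 scale (SE, edgeR adjusted p = 0.00375).

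Between Q88 and CTRL in F, 251 of 10503 genes passed the edgeR test, 127 higher and 124 lower in Q88, of which 64 and 59 changed at least 2-fold. Complete separation was seen in 3.7% of tested genes, against 0.79% expected by chance, and held for each gene named by rank. The count was 469 with DESeq2, 421 with all 6 groups in one fit, 514 without CTRL F 3 and Q88 F 2 and 3719 with the cuticle maturation score as a covariate, where the digestive enzyme list lost its call (limma camera adjusted p = 0.223).

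In M, most genes of the unfolded protein response and accessory gland lists and part of the glutathione S-transferase genes were higher in Q88 than in CTRL, together with the serpin gene Spn75F, and Cyp4p2, Cyp6a2 and the neuropeptide gene AstCC were lower. Spn75F (FBgn0052203, chromosome 3L, 19128450 to 19129665) averaged 50.7 ± 6.44 CPM in Q88 and 4.78 ± 2.88 CPM in CTRL (SD, n = 5 each). For Spn75F the log2 change was 3.44 ± 0.30 (SE, edgeR adjusted p = 3.00e-06). Jon66Ci averaged 5.13 ± 1.38 CPM against 0.276 ± 0.204 CPM (SD, n = 5 each). For Jon66Ci the log2 change was 4.24 ± 0.51 (SE, edgeR adjusted p = 4.52e-05), and fit averaged 7.11 ± 4.88 CPM against 0.665 ± 0.283 CPM (SD, n = 5 each), a log2 change of 3.44 ± 0.43 (SE, edgeR adjusted p = 5.68e-05). Cyp6a2 averaged 23.4 ± 3.02 CPM against 198 ± 45.96 CPM (SD, n = 5 each). For Cyp6a2 the log2 change was -3.08 ± 0.21 (SE, edgeR adjusted p = 1.88e-07), and Cyp4p2 fell by 4.12 ± 0.21 on the log2 scale (SE). AstCC (FBgn0032337, chromosome 2L, 11083459 to 11085229) had 12 reads in all Q88 libraries and a log2 change of -4.22 ± 0.80 (SE, edgeR adjusted p = 0.00185). The genes hll and Lime fell by 3.15 ± 0.35 and 2.68 ± 0.44 on the log2 scale (SE). DptA averaged 16.0 ± 25.3 CPM in Q88 and 2.05 ± 0.230 CPM in CTRL (SD, n = 5 each). For DptA the log2 change was 2.94 ± 0.95 (SE, edgeR adjusted p = 0.0485), and DptB rose by 3.08 ± 0.86 (SE, edgeR adjusted p = 0.0241). DptA lost its call without Q88 M 1 or 4 or any 1 CTRL library, and DptB without Q88 M 1 or CTRL M 2 or 3, with the highest edgeR adjusted p, 0.306 and 0.0860, without Q88 M 1. Both folds rest in part on Q88 M 1, which had 61.2 CPM of DptA where the other Q88 M libraries had 3.20 to 7.00, and without it the log2 changes were 1.201 for DptA and 2.26 for DptB.

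Of 18 genes of the unfolded protein response, 11 rose in Q88 M, or 12 adjusted over the list alone, with a median log2 change of 0.29 (limma camera adjusted p = 2.81e-07; adjusted p = 0.0886 with an estimated correlation). The chaperone genes of the endoplasmic reticulum Gp93 and Hsc70-3 rose by 0.62 ± 0.07 and 0.69 ± 0.09 and the disulphide isomerase genes CaBP1 and Pdi by 0.79 ± 0.10 and 0.48 ± 0.07 on the log2 scale (SE). Of 66 accessory gland genes, 42 rose and 1 fell, or 51 and 1 adjusted over the list alone (limma camera adjusted p = 1.05e-25; adjusted p = 0.359 with an estimated correlation), with Acp26Aa at 0.79 ± 0.13 and Spn77Bb at 1.75 ± 0.16 (log2, SE). Of 35 glutathione S-transferase genes, 12 rose and 2 fell, or 13 and 2 adjusted over the list alone (limma camera adjusted p = 2.70e-04; adjusted p = 0.679 with an estimated correlation), with GstD2 at 2.07 ± 0.20 and GstD4 at 1.95 ± 0.25 (log2, SE). Of 20 antioxidant genes, 8 rose, or 9 adjusted over the list alone (limma camera adjusted p = 0.0043; adjusted p = 0.359 with an estimated correlation), among them Gclm by 0.66, the thioredoxin reductase gene Trxr1 by 0.41 and Trx2 by 0.37 on the log2 scale. Of 28 lipid metabolism genes, 12 rose, and 12 rose and 1 fell adjusted over the list alone (limma camera adjusted p = 2.70e-04; adjusted p = 0.495 with an estimated correlation), with mag at 1.65 ± 0.26 (log2, SE) and the lipid droplet gene Lsd-2 at 0.65. Of 29 heat-shock genes, 7 rose, with the same count adjusted over the list alone (limma camera adjusted p = 0.0030; adjusted p = 0.679 with an estimated correlation), with Hsp70Bb at 1.30 ± 0.23 (log2, SE). Of 34 phototransduction genes, 9 fell and 2 rose, or 11 and 3 adjusted over the list alone (limma camera adjusted p = 0.0041; adjusted p = 0.380 with an estimated correlation), with ninaC at -1.10 ± 0.08 (log2, SE) and the rhodopsin gene Rh5 at -0.64.

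Between Q88 and CTRL in M, 1864 of 13072 genes passed the edgeR test, 1240 higher and 624 lower in Q88, of which 231 and 128 changed at least 2-fold. Complete separation was seen in 15.1% of tested genes, against 0.79% expected by chance, and held for each gene named by rank. CTRL M 5 stood apart from its arm and beside Q88, with 28.36 on the first principal component (Q88 18.25 to 29.85, other CTRL -15.82 to -10.12), a maturation score of -0.728 (Q88 -0.949 to -0.454) and a digestive enzyme score of 0.766 (Q88 0.402 to 0.722). Its accessory gland score of 0.338 was the highest of CTRL, below the lowest of Q88, 0.7375. Without CTRL M 5, 2338 genes passed. With the cuticle maturation score as a covariate 2927 genes passed, 1317 of them among the 1864 in the same direction. The limma camera calls of the heat-shock, glutathione S-transferase and lipid lists were then lost (adjusted p = 0.306, 0.347 and 0.0956).

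The difference between arms was then tested against sex in one fit of the 6 groups over 13421 genes, whose CPM differ slightly from those above because the libraries were scaled together. HSPBAP1 averaged 38.3 ± 9.08 CPM in WT M, against 2.55 ± 0.600 CPM in Q88 M and 2.76 ± 0.652 CPM in CTRL M (SD, n = 5 each), while its F group means lay between 5.27 and 5.89 CPM. Its log2 difference between Q88 and WT was lower in M than in F by -4.06 ± 0.31 (SE, edgeR adjusted p = 5.18e-09). In FBgn0010549 the order was the opposite, with 17.8 ± 2.14 CPM in Q88 F (SD, n = 5) and 15.1 ± 0.784 CPM in WT F (SD, n = 4) against 1.37 ± 0.354 CPM in CTRL F (SD, n = 5), and M group means between 2.92 and 3.69 CPM. The log2 difference from CTRL in M minus that in F was -3.75 ± 0.27 for Q88 (SE, edgeR adjusted p = 7.61e-10) and -3.78 ± 0.27 for WT (SE, edgeR adjusted p = 1.04e-09). The chitinase gene Cht5 averaged 15.5 ± 3.94 CPM in Q88 M and 213 ± 190 CPM in WT M (SD, n = 5 each), against 120 ± 83.3 CPM in Q88 F (SD, n = 5) and 55.8 ± 32.6 CPM in WT F (SD, n = 4), an interaction of -4.88 ± 1.40 (log2, SE, edgeR adjusted p = 0.0436). The Cht5 call was lost in 15 of 19 runs that left out 1 library, all but those without Q88 F 2 or 4 or WT M 3 or 4, with an edgeR adjusted p of at most 0.103. Ser12 had no reads in any M group, so its difference was not detectable there.

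Between the sexes, 573 genes differed in the response of Q88 against WT, 437 with the higher difference in M and 136 with the lower, a share of 76.3% higher that became 62.2% with RLE scaling and 55.6% with DESeq2. For Q88 against CTRL 429 genes differed, 353 and 76, a share of 82.3% higher that became 70.7% with RLE scaling and 66.4% with DESeq2. For WT against CTRL 58 genes differed, 21 and 37. Leaving out 1 library at a time gave 237 to 1145 genes, 137 to 545 and 25 to 97 in turn. Across the 10257 genes tested in both sexes, the log2 fold changes in F and in M had a correlation of 0.050 for Q88 against WT, 0.281 for Q88 against CTRL and 0.497 for WT against CTRL. These correlations are across genes, which are not independent replicates. Both sexes called 36 genes for Q88 against WT, 28 of them in one direction, where independent lists would share 17.3. The corresponding numbers were 144, 136 and 36.5 for Q88 against CTRL and 78, 75 and 20.3 for WT against CTRL.

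The comparisons of Q88 and of WT with CTRL shared their control libraries, and the overlap of their calls was therefore set beside simulated groups with no effect. In F, 46 genes were higher and 33 lower in both arms than in CTRL, where independent lists would share 1.2 and 0.6, and 1 gene was called in opposite directions. In M, 387 were higher and 233 lower in both, where independent lists would share 97.0 and 68.1, and 38 were called in opposite directions. The 20 simulations with no effect gave a mean of 0 shared calls in either sex. Their genes were drawn independently and without an effect, where hardly any gene is called. This count could therefore hardly differ from 0 and does not test the overlap. Across genes, the correlation of the fold changes was 0.488 in F and 0.467 in M, against simulated means of 0.469 and 0.502, and the covariance was 0.067 and 0.087 against 0.035 and 0.016. The share of genes with the same sign in both comparisons was 45.3% in F and 62.3% in M, against simulated means of 65.5% and 66.7%. With separate CTRL libraries for each arm, over 10 splits of the controls, the means were 18.7 genes higher and 17.7 lower in both arms in F, and 137.9 and 85.1 in M. In these splits the correlation averaged 0.159 in F (range -0.175 to 0.343) and 0.369 in M (range 0.25 to 0.538). The covariance averaged 0.027 in F (range -0.052 to 0.063) and 0.081 in M (range 0.061 to 0.107). Cyp4p2, Cyp6a2 and LysD were lower, and Hsp68 and Hsp70Bb higher, than CTRL in both arms and both sexes.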

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

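The tests of the cuticle maturation score as the cause of all calls, of its bearing on the heat-shock genes, the test of transgene reads and the test of shared control libraries were chosen only after the results were seen.

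In M, 2850 genes differed between Q88 and WT, and the cuticle maturation score also differed between these arms, by -1.02. Of 1200 called genes with a slope on the score within arms, 1147, or 95.6%, differed between the arms in the direction that the slope and the score difference predict, so a difference in maturation, for example in age after eclosion, may lie behind part of the calls. With the score as a covariate 838 calls, or 29.4%, kept their direction and passed. The score is an imperfect measure from a list chosen on these samples, so this cannot decide whether maturation lies behind all of the calls. Library size was argued against by close mean total counts, 14730000 in Q88 M and 15150000 in WT M. After all M libraries had been thinned to 12260798 counts 2687 calls remained, but with such totals this test could hardly fail. The labels do not spell out what the WT arm carries, and an effect of the repeat on the same genes or on maturation itself stays open and was not tested.

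Of the heat-shock list, 10 of 27 genes in F and 16 of 29 in M were higher in WT than in CTRL. Reads from hsp70 sequence carried by a transgene were argued against as the whole cause, because 4 list members outside the Hsp70 copies rose in both F and M, namely DnaJ-1 (0.83 and 0.84 on the log2 scale), Hsp67Bc (2.07 and 2.55), Hsp23 (1.53 and 1.49) and Hsp68 (2.39 and 2.33). As far as the score measures it, a difference in maturation was argued against in F, since 14 list members rose there with the score as a covariate. In M the score was also fitted as a covariate, but no limit on the heat-shock genes was set there. The question therefore stays open in M. There the heat-shock score was highest in WT M 3 and 4, at 1.09 and 0.736. These libraries had the lowest maturation scores of WT M, at -0.836 and -0.167. Transgene reads within the counts of the Hsp70 copies, an effect of a transgene in the WT arm, which the labels do not spell out, a difference in handling or temperature, and strain background stay open and were not tested.

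A set of 34 genes differed from CTRL in the same direction in both other arms and both sexes, 19 higher and 15 lower than CTRL. The shared control libraries alone were argued against, since at least 13 of the 34 genes kept their direction and call in all 4 comparisons when each arm had its own CTRL libraries, over 100 pairs of an F and an M split (highest 20). The bound first set for this test rested on simulations that gave 0 such genes and was dropped, because it could hardly fail. Linked strain variants stay open, with 3 pairs of such genes within 200 kb, where 10000 random sets had a median of 2 and a highest value of 12. The bound set before the test, which would have excluded them at this count, was wrong, because a count above the random median forbids no linkage and because neighbours of one gene family, such as Cyp4p1 and Cyp4p2, were left out. Linked or unlinked variants between the CTRL flies and those of both other arms may account for the set, as may anything else these arms share, and the labels give no strain.

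Chance was tested by splitting the same samples in other ways. For Q88 against WT, 1 of 100 splits, the labelled one, gave as many genes in F (82, with 0 as the highest other) and 1 of 100 in M (2850, with 1 as the highest other). This argues against a chance split of these samples, and 1 of 100 is the least that the test can give. Chance differences between pools of flies cannot be excluded by it, because the labels do not say that the libraries came from separate pools. The same held for WT against CTRL in F (1 of 100, 148 genes, highest other 89) and in M (1 of 100, 2450 genes, highest other 549) and for Q88 against CTRL in M (1 of 100, 1864 genes, highest other 5). For Q88 against CTRL in F, 4 of 100 splits gave as many as 251 genes, which met the limit set before. Yet 1 other split called 4306 genes, which points to a structure of the F samples other than the arms, so chance cannot be called excluded. With the cuticle maturation score as a covariate, Q88 against WT in F called 2871 genes, reached by 3 of 100 splits, of which the highest other called 3967. Among gene lists, the limit was met for Q88 against WT in M (1 of 100 splits with as many as 20 lists), but by a narrow margin (highest other 18, median 11). Chance was not excluded for Q88 against WT in F (17 splits with as many as 22 lists, highest other 28), Q88 against CTRL in F (69 splits, 12 lists, highest other 22), WT against CTRL in F (98 splits, 3 lists, highest other 26), Q88 against CTRL in M (20 splits, 13 lists, highest other 20) or WT against CTRL in M (11 splits, 16 lists, highest other 19).

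The response of the arms differed between the sexes, by the edgeR interaction test, in 573 genes for Q88 against WT, 429 for Q88 against CTRL and 58 for WT against CTRL. Among 40 splits, 1 gave as many for Q88 against WT (highest other 0) and 1 for WT against CTRL (highest other 5), while 4 did so for Q88 against CTRL (highest other 1921), where chance was not excluded. The log2 difference in M minus that in F for Q88 against WT was -4.88 for Cht5, -4.32 for slow and -4.06 for HSPBAP1. It was also 5.42 for PpD6, 5.03 for gskt and 4.10 for SkpF, which had 0 reads in Q88 F and at most 14 in WT F, so that these values rest on traces. When 1 library was left out, slow lost its call in 4 of 19 runs (without WT F 4 or 5 or WT M 1 or 5) and SkpF in 13 (all but those without Q88 F 4, Q88 M 4, WT F 1 or 4 or WT M 3 or 4), with an edgeR adjusted p of at most 0.0605 and 0.22. For Q88 against CTRL it was 5.54 for Spn75F, 3.50 for Sgp, 2.97 for MFS1, -4.83 for Cht5, -3.75 for FBgn0010549 and -3.03 for salto, of which Spn75F stayed under 1 CPM in F and salto averaged 0.780 CPM in Q88 F and 0.0886 CPM in CTRL F. Here Sgp and Cht5 each lost the call in 17 of 20 runs, all but those without CTRL F 1 or 5 or Q88 F 1 for Sgp and without CTRL F 3, CTRL M 5 or Q88 F 2 for Cht5, with an adjusted p of at most 0.136 and 0.14. For WT against CTRL it was 4.50 for Spn75F, 3.88 for HSPBAP1, 3.06 for Cnx14D, -3.99 for PpD6, -3.78 for FBgn0010549 and -2.97 for Dpy-30L2, of which Spn75F, Cnx14D, PpD6 and Dpy-30L2 stayed under 1 CPM in F. These 4 lost the call in 13, 2, 12 and 15 of 19 runs, with an adjusted p of at most 0.166, 0.0758, 0.166 and 0.411. Cnx14D lost it without WT F 3 or 5. The call held for Spn75F only without CTRL F 5, CTRL M 1, 3 or 4, WT F 3 or WT M 3, for PpD6 only without CTRL F 2, CTRL M 2, 3 or 4 or WT M 3, 4 or 5, and for Dpy-30L2 only without CTRL F 5, CTRL M 4, WT F 1 or WT M 3.

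Single libraries stood far from the others of their group in 10 of 182 groups of values, where chance gives 9.1. They were chrb in WT F 1 (186 CPM, others 174 to 175), Gug in WT F 1 (242 CPM, others 199 to 202), Ser12 in CTRL F 3 (0.135 CPM, others 0) and Hsp68 in CTRL F 5 (95.8 CPM, others 138 to 159). In M they were PpD6 in Q88 M 3 (7.75 CPM, others 9.44 to 9.88), DptA in Q88 M 1 (61.2 CPM, others 3.20 to 7.00), Cyp6a2 in CTRL M 5 (278 CPM, others 167 to 186) and Gug in CTRL M 5 (72.1 CPM, others 107 to 117). Drsl3 had 0 CPM in WT M 1, with the others at 0.0594 to 0.0728, and the cuticle maturation score was -0.728 in CTRL M 5, with the others at 0.415 to 0.766.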

How the results depend on the processing

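The cuticle maturation score as a covariate and the removal of both F libraries at the ends of the first component (CTRL F 3 and Q88 F 2) were chosen after the data had been seen. Of 1843 recomputed values of named genes, 1642 kept their direction and side of the threshold, 198 lost it, 1 gained it and 2 changed direction, both of Gug, which was not called. RLE scaling moved no total count of genes or lists by over 1.5 times, though the shares of higher differences in the interactions changed as given above. The absence of a filter on low counts was tried for genes only and moved no total count of genes by over 1.5 times. Where counts moved, the cause was not tested, except that a run without a library has fewer samples. F libraries varied more than M libraries, and the test on simulated counts found 17.9% to 29.9% of genes changed 1.5-fold in F, where it found 55.2% to 65.7% in M.

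Replicate numbers were tried as a block. Whether they pair the samples is not known. Of 28 pairs of libraries with the same number, 14 correlated above 0.1 in their deviations from the arm means, in a range from -0.301 to 0.687. Pairs with different numbers were not compared, so this count cannot decide it. The block gave 46 genes for Q88 against WT in F, where 82 passed without it, and 35 for the interaction of WT against CTRL, where 58 passed without it. No other count moved by over 1.5 times with the block.

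DESeq2 called 330, 469 and 305 genes in F for Q88 against WT, Q88 against CTRL and WT against CTRL, where edgeR called 82, 251 and 148, and 1033 and 102 genes for the interactions of Q88 against WT and WT against CTRL, where edgeR called 573 and 58. All 6 groups in one fit gave 227, 421 and 258 genes for the F comparisons, 1410 for Q88 against WT in M and 719 for WT against CTRL in M. Only the 2 compared arms in the fit gave 1034 for WT against CTRL in M. Without CTRL F 3 and Q88 F 2 the F counts were 163, 514 and 399. With the maturation score they were 2871, 3719 and 477 in F, 1167, 2927 and 3942 in M for the comparisons in the same order, and 874, 2182 and 449 for the interactions.

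Calls of gene lists fell to 0, 0 and 1 in F and 0, 0 and 0 in M with an estimated correlation in limma camera, from 22, 12 and 3 in F and 20, 13 and 16 in M. By fry they numbered 3, 1 and 2 in F and 18, 14 and 10 in M. With the maturation score, 20 lists were called for Q88 against CTRL in F and 1 for WT against CTRL in F.

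Leaving out each library in turn gave 35 to 95 genes for Q88 against WT in F, 175 to 284 for Q88 against CTRL in F, 92 to 199 for WT against CTRL in F, 1675 to 3778 for Q88 against WT in M, 1371 to 2338 for Q88 against CTRL in M and 1503 to 3047 for WT against CTRL in M. The interactions gave 237 to 1145, 137 to 545 and 25 to 97 genes. For the interaction of Q88 against WT, the count was 1145 without Q88 F 4, 380, 349 and 353 without Q88 M 1, 3 and 5, 381, 237 and 380 without WT F 3, 4 and 5, and 295, 309, 1077, 929 and 354 without WT M 1 to 5. For that of Q88 against CTRL it was 276 without CTRL F 1, 152, 137, 207 and 188 without CTRL M 1 to 4, and 173, 203, 152, 224 and 172 without Q88 M 1 to 5. For that of WT against CTRL it was 36 and 33 without CTRL F 1 and 2, 36 and 35 without CTRL M 1 and 5, 35 and 25 without WT F 1 and 5, and 35 and 97 without WT M 1 and 3. The libraries that moved the counts of single comparisons by over 1.5 times stand beside those counts.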

Other observations

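The list of adult cuticle maturation and its tests were chosen after the data had been seen, and so were the genes Pp1-Y1, w and Or45a and those singled out from the set that differed from CTRL. In M, 7 of 28 autophagy and lysosome genes fell in Q88 against WT, and 8 fell and 1 rose adjusted over the list alone (limma camera adjusted p = 7.30e-04; adjusted p = 0.342 with an estimated correlation). Atg2 fell by 0.38 ± 0.06, Atg101 by 0.51 ± 0.08 and the cathepsin gene CtsL1 by 0.52 ± 0.09 on the log2 scale (SE). Of 9 measured genes of Atrophin and its partners, 3 fell in the same comparison and 5 adjusted over the list alone (limma camera adjusted p = 0.0286; adjusted p = 0.541 with an estimated correlation), namely tsh by 0.46 ± 0.09, hth by 0.32 ± 0.08 and the histone methyltransferase gene G9a by 0.28 ± 0.08 on the log2 scale (SE). In WT M, hth and tsh were higher than in CTRL M, by 0.28 ± 0.08 and 0.255 ± 0.084 (log2, SE, edgeR adjusted p = 0.0313 and 0.0452). No other member of this list passed between WT and CTRL in M. For Q88 against WT, the call of the Atrophin list was lost with the cuticle maturation score as a covariate (limma camera adjusted p = 0.518). Of 31 UDP-glycosyltransferase genes, 9 rose and 1 fell, or 10 and 2 adjusted over the list alone (limma camera adjusted p = 0.0286; adjusted p = 0.412 with an estimated correlation), with Ugt37A2 at 1.06 ± 0.16 and Ugt37B1 at 1.01 ± 0.17 (log2, SE). Of 33 genes of Toll and Imd signalling, 9 rose and 1 fell in Q88 against CTRL, or 9 and 3 adjusted over the list alone, with no call (limma camera adjusted p = 0.428; adjusted p = 0.904 with an estimated correlation), and those that rose included PGRP-SD at 1.10 ± 0.16 and the NF-kappaB gene Rel at 0.58 ± 0.11 (log2, SE). Of 15 yolk and starvation-linked fat-body genes, 3 rose in Q88 against CTRL, with the same count adjusted over the list alone (limma camera adjusted p = 0.0105; adjusted p = 0.359 with an estimated correlation), namely fit, Fst at 2.21 ± 0.35 and the larval serum protein gene Lsp2 at 1.02 ± 0.25 (log2, SE).

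Part of the genes that mark the last steps of cuticle formation after eclosion were lower in Q88 M than in WT M. Of 14 such genes, 8 fell, or 9 adjusted over the list alone, and as the list was chosen on these samples its count is not independent evidence. The log2 changes were -3.81 ± 0.85 for Cht5, -4.03 ± 0.92 for the bursicon subunit gene Pburs, -1.03 ± 0.29 for its receptor gene rk and -1.44 ± 0.42 for the chitin synthase gene kkv (SE, edgeR adjusted p = 0.00631, 0.00710, 0.0231 and 0.0263). Pburs was near the floor, at up to 0.149 CPM in Q88 M and from 0.146 to 3.58 CPM in WT M. The other subunit gene of the list, Burs, was chosen after its values were seen. It was not lower, with means of 1.715 CPM in Q88 M and 1.675 CPM in WT M. Within F the score varied mainly inside the arms, at -0.269 ± 0.966 in CTRL (SD, n = 5), 0.121 ± 1.14 in Q88 (SD, n = 5) and 0.186 ± 0.435 in WT (SD, n = 4), and it was 1.33 in CTRL F 3 and -1.71 in Q88 F 2, the libraries at the ends of the first component.

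The Y-linked phosphatase gene Pp1-Y1 was higher than CTRL by 8.03 ± 0.38 in Q88 M and by 8.20 ± 0.37 in WT M (log2, SE, edgeR adjusted p = 1.64e-07 and 8.07e-08). The eye pigment gene w was higher than CTRL by 0.53 ± 0.06 in Q88 M and 0.52 ± 0.06 in WT M (log2, SE, edgeR adjusted p = 1.97e-05 and 4.25e-05). In F, w did not pass against CTRL, at 0.332 ± 0.155 in Q88 and 0.383 ± 0.164 in WT (log2, SE, edgeR adjusted p = 0.494 and 0.522). The odorant receptor gene Or45a was higher than CTRL by 3.15 ± 0.40 in Q88 M and 2.98 ± 0.40 in WT M (log2, SE). Among the 34 genes that differed from CTRL in both arms and both sexes, CG18853 was higher by 4.13 and 4.01 in Q88 F and WT F and by 4.55 and 4.39 in Q88 M and WT M, and CG31380 differed by -6.18, -6.34, -2.28 and -2.38 in the same order (log2). Ubi-p63E, a polyubiquitin gene, was higher by 0.73 and 0.84 in F and by 0.63 and 0.75 in M (log2).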
